A study of Rattus norvegicus with 30 samples.

How the data were processed

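RNA was measured in 30 cultures of frozen male Sprague Dawley rat hepatocytes, 5 for each of 6 groups: DMSO, labelled as 1%, 3 uM or 100 uM methapyrilene for 24 or 48 h. Per the labels, RNA was isolated with Tri-Reagent and an RNeasy kit, labelled with biotin and hybridised to a rat whole-genome expression array. The deposited values are intensity, which the authors made with MAS5 as a probe set signal on a linear scale; its version and any detection calls are not stated. In the deposited values the 2% trimmed mean over the 31099 probe sets was 1499.94 on every array, while medians ranged from 361.677 to 471.419, so arrays had been scaled but not made alike in distribution. The number of arrays limits the precision, and no depth applies.

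Probe sets took the gene of the platform's annotation, with symbols updated through the gene identifier to the current rat gene table. Of these, 20826 had 1 symbol, 436 several and 9780 none, and 57 were controls. The values were log2 transformed without a pseudocount. A probe set was kept where at least 5 arrays exceeded their own median, which left 17555, and each gene was represented by its probe set with the highest mean, which gave 10222 genes. The 4025 probe sets past the filter without exactly 1 symbol were tested apart. Left out were the controls, the probe sets below the filter and the dimmer probe sets of the 2546 genes that had over 1.

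Genes were tested with limma 3.58.1 in R 4.3.3. A mean per group was fitted to all 30 arrays (24 residual degrees of freedom), with eBayes and a trend, and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called at an adjusted p under 0.05. The comparisons were each dose with DMSO at each time, the doses with each other, DMSO at 48 h with 24 h, and the change of each dose's effect between the times. All tests were two-sided. The wells were not paired, because the replicates are numbered in the order of deposit and nothing links a well of one group to a well of another. Array numbers in the titles fall in runs of 6 that hold 1 array of each group, and a fit with these runs as blocks was an alternative.

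Gene lists (33, with 917 genes) and the rule for naming genes were fixed before the data were examined, as were the comparisons and most alternatives. The rule names the 10 largest changes each way among called genes whose 5 treated arrays all lie on one side of all 5 DMSO arrays, plus up to 4 called members of each list by adjusted p, or the 2 brightest where none passed. For time and for the interactions it names 6 each way. Lists with at least 5 measured genes (31) were tested with limma's camera at a preset correlation of 0.01, which asks whether a list moves apart from the other genes. The alternatives were an estimated correlation and fry, which asks only whether a list moves one way. The 2 lists with fewer were histamine receptors and metabolism, and markers of sinusoidal endothelial cells. List calls kept with an estimated correlation numbered 1 of 7 at 3 uM and 24 h, 11 of 23 at 100 uM and 24 h, 1 of 9 at 3 uM and 48 h and 15 of 23 at 100 uM and 48 h.

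Overlap of calls was compared with the product of the 2 counts divided by the genes, and correlations of log2 fold changes with those of simulated unchanged groups that share the same controls (100 draws) and with DMSO arrays split between the doses. Alternatives changed the scaling (quantile, median), filter, floor, pseudocount (16), probe sets per gene, variance model, arrays in the fit, array weights, array order, thresholds (0.01, 1.5-fold) and each array in turn. Chosen after seeing the data were 3 uM at 24 h with replicates 4 and 5 alone, 100 uM at 48 h without replicate 3, and the log2 ratio of the 3' to 5' beta-actin control probe sets as a covariate. Other splits of the arrays were drawn 100 times for each comparison.

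The pipeline was tested on simulated data made from the arrays' own values. With 200 genes of 10222 changed, 73.1% of those changed 1.5-fold and 95.5% of those changed 2-fold were recovered with 6 false calls. With nothing changed, limma called 0 genes in each of the 9 comparisons. Of 200 unshifted lists of random genes, 9 had a camera p under 0.05. The arrays' deviations were shuffled over all groups, so these checks do not cover arrays of 1 group that stand apart together. Random lists do not test the preset correlation for genes that move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.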

Results

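Methapyrilene is an antihistamine that was withdrawn after it was found to cause liver tumours in rats. The study asked how it changes gene expression in primary rat hepatocytes. Thawed hepatocytes of male Sprague Dawley rats were cultured, dosed on day 3 with 3 uM or 100 uM methapyrilene or with DMSO as the vehicle, and harvested after 24 or 48 h. The labels give 1% DMSO, but the protocol describes the concentrated dosing solutions as being in 1% DMSO, so the share in the medium is uncertain. Each of the 6 groups had 5 arrays, so n = 5 in every group below and the 30 arrays limit the precision. The replicates are separate wells of purchased frozen cells, described in the labels as independent cultures, and the labels name no animals, so the p-values measure the spread between wells. Other compounds of the same programme were studied at other times and are not used here.

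After the deposited scaling the median signal of an array lay between 362 and 471. The first principal component held 25.3% of the variance and put all arrays of 100 uM apart, with scores from 19.6 to 25.9 against -16.7 to -6.35 in the others. The second held 8.97% and put replicates 1, 2 and 3 of 3 uM at 24 h apart, with scores from 20.4 to 24.9 against 5.22 and 1.41 in replicates 4 and 5. In the same 3 arrays the ratio of the 3' to the 5' control probe set of beta-actin, which rises when RNA or its labelled copy is shortened, was 3.93, 5.10 and 5.30. It lay between 2.34 and 3.43 in the other 27 arrays. The same ratio for the GAPDH control was 1.15, 1.21 and 1.24 in these 3 arrays. Replicates 2 and 3 lay above all other arrays (up to 1.17), and replicate 1 did not. Values below are mean signals ± SD or log2 fold changes ± SE.

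**Figure D1:**
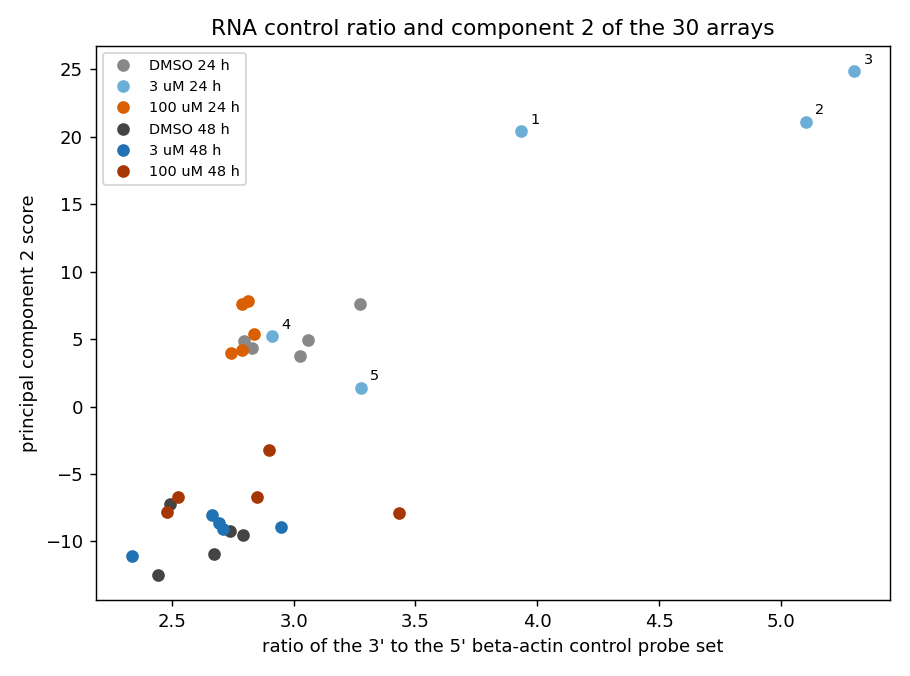
Each point is one of the 30 arrays, with the ratio of the 3' to the 5' beta-actin control probe set on the horizontal axis and the score on principal component 2 on the vertical axis, coloured by group; digits are the replicates of 3 uM at 24 h. Replicates 1, 2 and 3 of that group lie apart at ratios of 3.93, 5.10 and 5.30.

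At 100 uM, hepatocytes at 24 h held less RNA of many metabolic enzymes. Bhmt, which remethylates homocysteine in the liver, fell from 53636 to 9658, a log2 fold change of -2.48 ± 0.11 (adjusted p = 2.85e-18). Of the amino acid catabolism genes, 28 of 32 fell and 0 rose, or 30 and 0 adjusted over the list alone, with a median of -0.83 (adjusted p = 1.24e-27). Among them were Aass of lysine breakdown (-2.14 ± 0.094) and Kynu of tryptophan breakdown (-1.67 ± 0.082). Nr1i3, the nuclear receptor CAR, fell too (-2.37 ± 0.16, signal 418 ± 107 against 2167 ± 555).

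Bile acid genes moved the same way: 13 of 17 fell and 1 rose, or 13 and 1 adjusted over the list alone (adjusted p = 2.09e-09). Cyp8b1, which makes cholic acid, changed by -2.12 ± 0.087 and Slc10a1, the bile salt uptake transporter, by -1.61 ± 0.13. Of the cytochrome P450 genes outside the other lists, 17 of 24 fell and 0 rose, or 18 and 0 adjusted over the list alone (adjusted p = 3.28e-10), led by Cyp4f4 (-1.41 ± 0.10) and Cyp2d2 (-0.78 ± 0.064). Of the gluconeogenesis and glucose handling genes, 11 of 18 fell and 0 rose, or 11 and 0 adjusted over the list alone (adjusted p = 6.29e-08), among them Pc, pyruvate carboxylase (-1.52 ± 0.10), and Slc37a4, the glucose 6-phosphate transporter (-1.11 ± 0.070). Of the fatty acid oxidation and PPAR-alpha target genes, 18 of 27 fell and 3 rose, or 18 and 3 adjusted over the list alone (adjusted p = 5.88e-07). Cyp4a1 was at -1.31 ± 0.092. Of the urea cycle genes, 7 of 8 fell and 1 rose, or 7 and 1 adjusted over the list alone (adjusted p = 4.94e-05). Arg1, arginase, was at -0.81 ± 0.075. Of the hepatocyte transcription factors, 9 of 16 fell and 0 rose, or 9 and 1 adjusted over the list alone (adjusted p = 7.28e-05). Nr1i2, the receptor PXR, was at -0.69 ± 0.080.

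Genes of other liver functions were lower too. Of the conjugation enzymes, 21 of 36 fell and 1 rose, or 21 and 1 adjusted over the list alone (adjusted p = 1.68e-06, and adjusted p = 0.131 with an estimated correlation). Sult1b1 was at -0.72 ± 0.079. Of the genes of secreted plasma proteins, 19 of 38 fell and 0 rose, or 19 and 0 adjusted over the list alone (adjusted p = 1.26e-07, and adjusted p = 0.131 with an estimated correlation). Apob, the LDL apolipoprotein, was at -0.77 ± 0.089 and complement C3 at -0.52 ± 0.064. Of the acute phase genes, 10 of 25 fell and 1 rose, or 10 and 1 adjusted over the list alone (adjusted p = 0.00879, and adjusted p = 0.131 with an estimated correlation); Steap4 fell (-1.84 ± 0.12) while Hamp, the iron hormone hepcidin, rose (1.24 ± 0.14). Of the genes of fatty acid and triglyceride synthesis, 7 of 18 fell and 1 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.00414, and adjusted p = 0.181 with an estimated correlation). Thrsp was at -1.20 ± 0.10. Of the endoplasmic reticulum chaperones, 10 of 26 fell and 1 rose, or 12 and 3 adjusted over the list alone (adjusted p = 0.00756, and adjusted p = 0.117 with an estimated correlation). Hsp90b1 was at -0.40 ± 0.055. Of the nuclear-encoded oxidative phosphorylation genes, 8 of 52 fell and 0 rose, or 6 and 0 adjusted over the list alone. This share called lower was near that over all genes, 1618 of 10222. In camera the list lay lower by little (median -0.035, adjusted p = 0.0382, and adjusted p = 0.670 with an estimated correlation).

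Higher at 24 h were lists that included p53 targets, ribosome biogenesis and heat shock genes. Of the p53 targets, 9 of 20 rose and 2 fell, or 12 and 2 adjusted over the list alone (adjusted p = 0.000601); Mdm2, which holds p53 in check, rose from 3901 to 9458 (1.28 ± 0.060, adjusted p = 1.89e-17), and the nuclease Aen rose by 1.26 ± 0.068. Of the ribosome biogenesis genes, 25 of 31 rose and 0 fell, or 26 and 0 adjusted over the list alone (adjusted p = 1.03e-10). Nop56 was at 0.58 ± 0.055 and nucleolin, Ncl, at 0.42 ± 0.050. Of the heat shock genes, 10 of 16 rose and 0 fell, or 11 and 0 adjusted over the list alone (adjusted p = 3.49e-05). Hspb8 was at 0.64 ± 0.047. Of the cell cycle and DNA replication genes, 14 of 30 rose and 1 fell, or 14 and 1 adjusted over the list alone (adjusted p = 0.00756). Pcna, the replication clamp, was at 0.71 ± 0.062 and Cks2 at 0.84 ± 0.078. Of the proteasome genes, 23 of 34 rose and 1 fell, or 25 and 1 adjusted over the list alone (adjusted p = 1.45e-06, and adjusted p = 0.115 with an estimated correlation). Psmd5 was at 0.51 ± 0.055. Of the ATF4 and integrated stress response genes, 19 of 39 rose and 7 fell, or 21 and 7 adjusted over the list alone (adjusted p = 0.0118, and adjusted p = 0.150 with an estimated correlation); Ddit3, the stress factor CHOP, rose (1.07 ± 0.072) while Herpud1 (-0.66 ± 0.049) and Cth (-0.90 ± 0.076) fell. Of the NRF2 targets, 16 of 32 rose and 3 fell, or 16 and 4 adjusted over the list alone (adjusted p = 0.0190, and adjusted p = 0.317 with an estimated correlation). Gpx2 was at 0.65 ± 0.082 and Hmox1 at 0.46 ± 0.068. Of the cholesterol synthesis genes, 11 of 20 rose and 2 fell, or 12 and 5 adjusted over the list alone (adjusted p = 0.0443, and adjusted p = 0.332 with an estimated correlation). Cyp51 was at 0.76 ± 0.079 and Idi1 at 0.63 ± 0.070. Of the lysosome genes, 13 of 31 rose and 2 fell, or 13 and 2 adjusted over the list alone (adjusted p = 0.00942, and adjusted p = 0.117 with an estimated correlation). Cd63 was at 0.75 ± 0.074.

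Across the genome at 24 h, limma called 2029 of 10222 genes higher and 1618 lower at 100 uM (adjusted p under 0.05). Of these, 396 and 573 changed at least 1.5-fold, and 83 and 167 at least 2-fold. The brightest gene among the 10 largest increases was Nabp1, a single-stranded DNA binding protein (1.84 ± 0.075, signal 13995 ± 1532 against 3898 ± 420), followed by Sfn (1.60 ± 0.098). The naming rule also picked dim genes, whose DMSO or treated signals lay below the array medians, so that the size of the fold is uncertain: Ube2t rose (signal 383 ± 94.1 against 94.0 ± 61.3) and Abcc9 fell (signal 76.1 ± 70.9 against 468 ± 115).

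**Figure D2:**
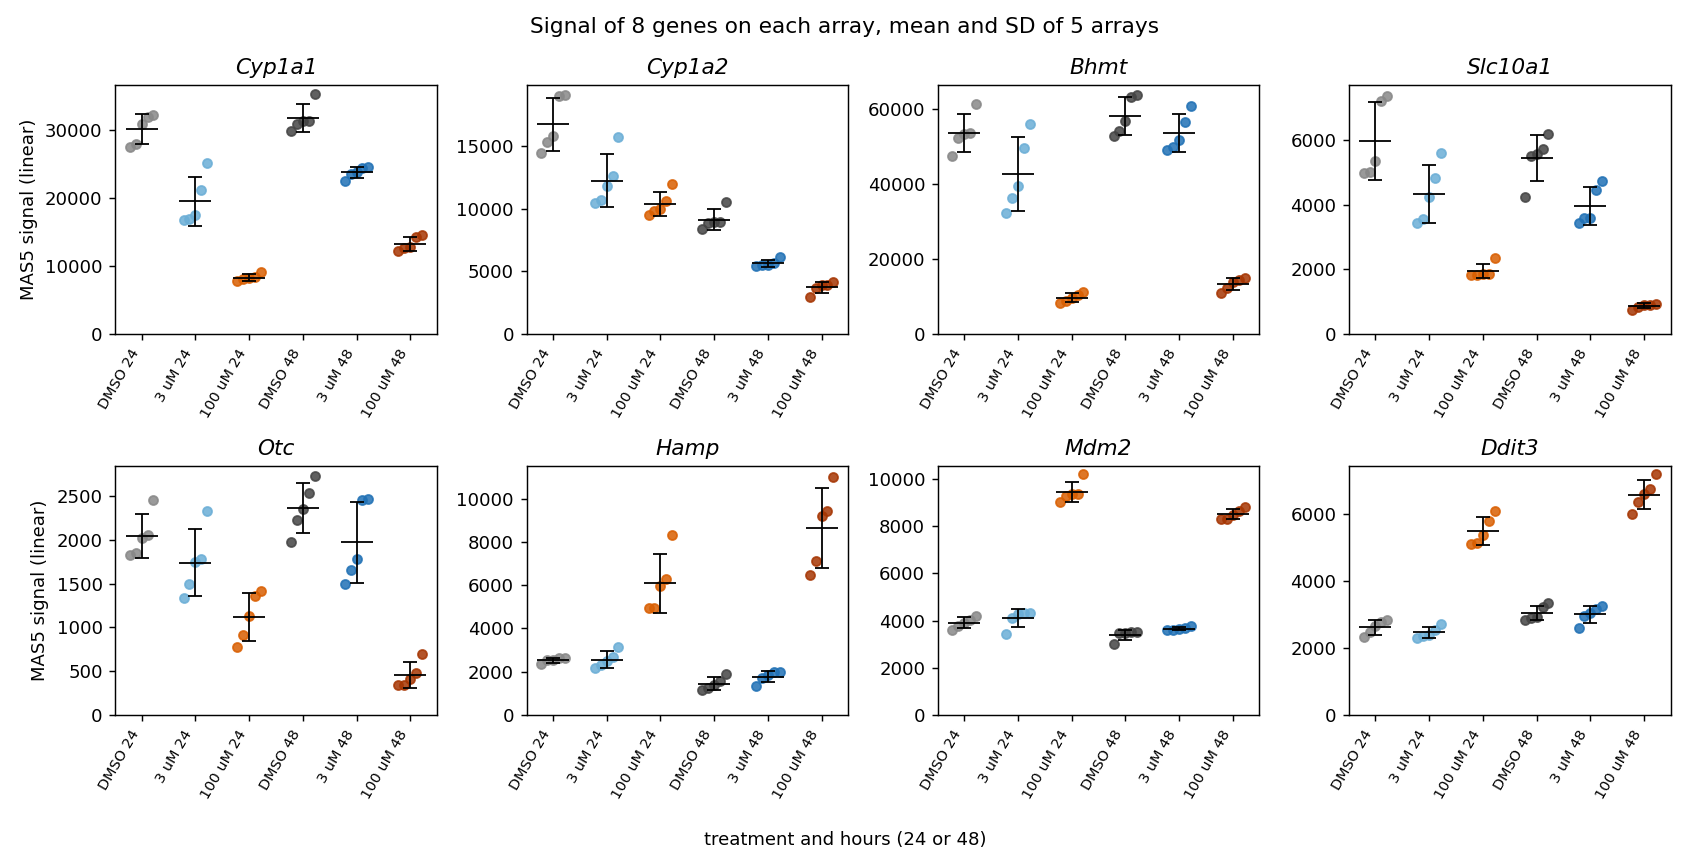
Points are the deposited signals of 8 genes on each of the 30 arrays, with the mean and SD of the 5 arrays of each group as black bars; the vertical axes are linear and start at 0. Mdm2 stands at 9458 at 100 uM and 24 h against 3901 in DMSO, and Bhmt at 9658 against 53636.

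At 48 h, 100 uM again lowered liver enzymes. Slc10a1 fell from 5449 to 867 (-2.65 ± 0.13, adjusted p = 3.11e-17), the carboxylesterase Ces1d from 6507 to 950 (-2.77 ± 0.14), and Otc, ornithine transcarbamylase of the urea cycle, from 2363 to 453 (-2.43 ± 0.18). Hamp rose from 1442 to 8646 (2.58 ± 0.14, adjusted p = 4.16e-16). Dennd5a rose by 1.90 ± 0.11, the enolase Eno2 by 1.80 ± 0.16 and the nuclease Dnase2b by 1.77 ± 0.097.

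Many lists of liver functions were lower at 48 h. Of the amino acid catabolism genes, 27 of 32 fell and 0 rose, or 27 and 0 adjusted over the list alone, with a median of -0.87 (adjusted p = 2.12e-25), among them Bhmt (-2.13 ± 0.11) and Fah, the last enzyme of tyrosine breakdown (-1.16 ± 0.059). Of the bile acid genes, 15 of 17 fell and 1 rose, or 15 and 1 adjusted over the list alone (adjusted p = 6.16e-13). Cyp8b1 was at -2.31 ± 0.087 and Baat, which conjugates bile acids, at -1.64 ± 0.16. Of the other P450 genes, 18 of 24 fell and 1 rose, or 18 and 2 adjusted over the list alone (adjusted p = 2.27e-14). Cyp2a1 was at -2.17 ± 0.10. Of the gluconeogenesis and glucose handling genes, 11 of 18 fell and 1 rose, or 11 and 1 adjusted over the list alone (adjusted p = 3.77e-09). Pklr, pyruvate kinase, was at -1.27 ± 0.10. Of the conjugation enzymes, 23 of 36 fell and 3 rose, or 25 and 3 adjusted over the list alone (adjusted p = 8.02e-11). Sult2a6 was at -2.50 ± 0.22. Of the fatty acid oxidation and PPAR-alpha target genes, 17 of 27 fell and 1 rose, or 18 and 1 adjusted over the list alone (adjusted p = 3.10e-10). Fabp1, the liver fatty acid binding protein, was at -1.96 ± 0.099. Of the genes of secreted plasma proteins, 24 of 38 fell and 1 rose, or 25 and 1 adjusted over the list alone (adjusted p = 6.16e-13). Coagulation factor F9 was at -0.80 ± 0.058. Of the urea cycle genes, 5 of 8 fell and 1 rose, or 5 and 1 adjusted over the list alone (adjusted p = 0.000948); Asl rose (0.29 ± 0.060).

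Other lists were also lower at 48 h. Of the hepatocyte transcription factors, 9 of 16 fell and 3 rose, or 9 and 3 adjusted over the list alone (adjusted p = 0.00520). Nr1i3 was at -1.96 ± 0.16 and, upward, Rora at 0.63 ± 0.098, a call that was lost with the mean of its probe sets (adjusted p = 0.692). Of the endoplasmic reticulum chaperones, 14 of 26 fell and 2 rose, or 15 and 2 adjusted over the list alone (adjusted p = 0.000190). P4hb was at -0.46 ± 0.048. Of the acute phase genes, 10 of 25 fell and 1 rose, or 11 and 1 adjusted over the list alone (adjusted p = 0.00310, and adjusted p = 0.0842 with an estimated correlation). Crp, C-reactive protein, was at -1.40 ± 0.12. Of the CAR and PXR targets, 9 of 17 fell and 4 rose, or 9 and 4 adjusted over the list alone (adjusted p = 0.0137, and adjusted p = 0.156 with an estimated correlation), with Cyp3a18 lower (-1.42 ± 0.097) and Abcc2, an export pump, higher (0.57 ± 0.063). Of the fatty acid and triglyceride synthesis genes, 8 of 18 fell and 2 rose, or 8 and 3 adjusted over the list alone (adjusted p = 0.00293, and adjusted p = 0.156 with an estimated correlation). Acly was at -0.80 ± 0.073. Of the cholesterol synthesis genes, 8 of 20 fell and 1 rose, or 9 and 1 adjusted over the list alone (adjusted p = 0.0213, and adjusted p = 0.270 with an estimated correlation). Hsd17b7 was at -0.86 ± 0.091. Of the oxidative phosphorylation genes, 13 of 52 fell and 0 rose, or 13 and 0 adjusted over the list alone (adjusted p = 0.00520, and adjusted p = 0.574 with an estimated correlation). Sdha was at -0.24 ± 0.049. Markers of cholangiocytes, the bile duct cells, were lower alongside: 4 of 6 fell and 0 rose, or 4 and 0 adjusted over the list alone (adjusted p = 0.0310, and adjusted p = 0.0751 with an estimated correlation).

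Ribosome biogenesis, proteasome, heat shock, p53, cell cycle and lysosome genes were higher at 48 h. Of the ribosome biogenesis genes, 23 of 31 rose and 0 fell, or 23 and 0 adjusted over the list alone (adjusted p = 6.89e-08). Wdr12 was at 0.62 ± 0.080. Of the proteasome genes, 21 of 34 rose and 0 fell, or 21 and 0 adjusted over the list alone (adjusted p = 6.37e-06, and adjusted p = 0.102 with an estimated correlation). Psmc6 was at 0.41 ± 0.053. Of the heat shock genes, 10 of 16 rose and 1 fell, or 12 and 2 adjusted over the list alone (adjusted p = 0.000529). Hspb1 was at 0.79 ± 0.11. Of the p53 targets, 10 of 20 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 0.00193). Mdm2 was at 1.33 ± 0.060. Of the cell cycle genes, 12 of 30 rose and 2 fell, or 12 and 2 adjusted over the list alone (adjusted p = 0.00825). Tyms, thymidylate synthase, was at 0.81 ± 0.12 and Tk1 lower at -0.68 ± 0.093. Of the lysosome genes, 13 of 31 rose and 3 fell, or 15 and 3 adjusted over the list alone (adjusted p = 0.00310, and adjusted p = 0.0615 with an estimated correlation). Npc2 was at 0.63 ± 0.051 and Scarb2 at 0.69 ± 0.065. Cd68, a lysosomal protein used as a macrophage marker, rose by 1.65 ± 0.12, while of the Kupffer cell and leukocyte markers 2 of 13 rose and 1 fell, or 1 and 0 adjusted over the list alone (adjusted p = 0.378, and adjusted p = 0.524 with an estimated correlation). The ATF4 and NRF2 lists were not called at 48 h: of the ATF4 genes, 6 of 39 rose and 12 fell, or 6 and 12 adjusted over the list alone (adjusted p = 0.113, and adjusted p = 0.362 with an estimated correlation), and of the NRF2 targets, 8 of 32 rose and 7 fell, or 8 and 9 adjusted over the list alone (adjusted p = 0.596, and adjusted p = 0.784 with an estimated correlation).

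Across the genome at 48 h, limma called 1932 genes higher and 1483 lower, 347 and 510 of them at least 1.5-fold and 76 and 179 at least 2-fold. With each array centred on its median, 44.6% of the calls were upward, against 56.6% in the deposited scaling, and at 24 h 47.5% against 55.6%. For Yme1l1 (0.26 ± 0.046) and Clock (0.35 ± 0.086) another probe set was called in the opposite direction, and for Psmd9 (0.45 ± 0.082) and Yme1l1 the mean of all probe sets had the other sign.

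**Figure D3:**
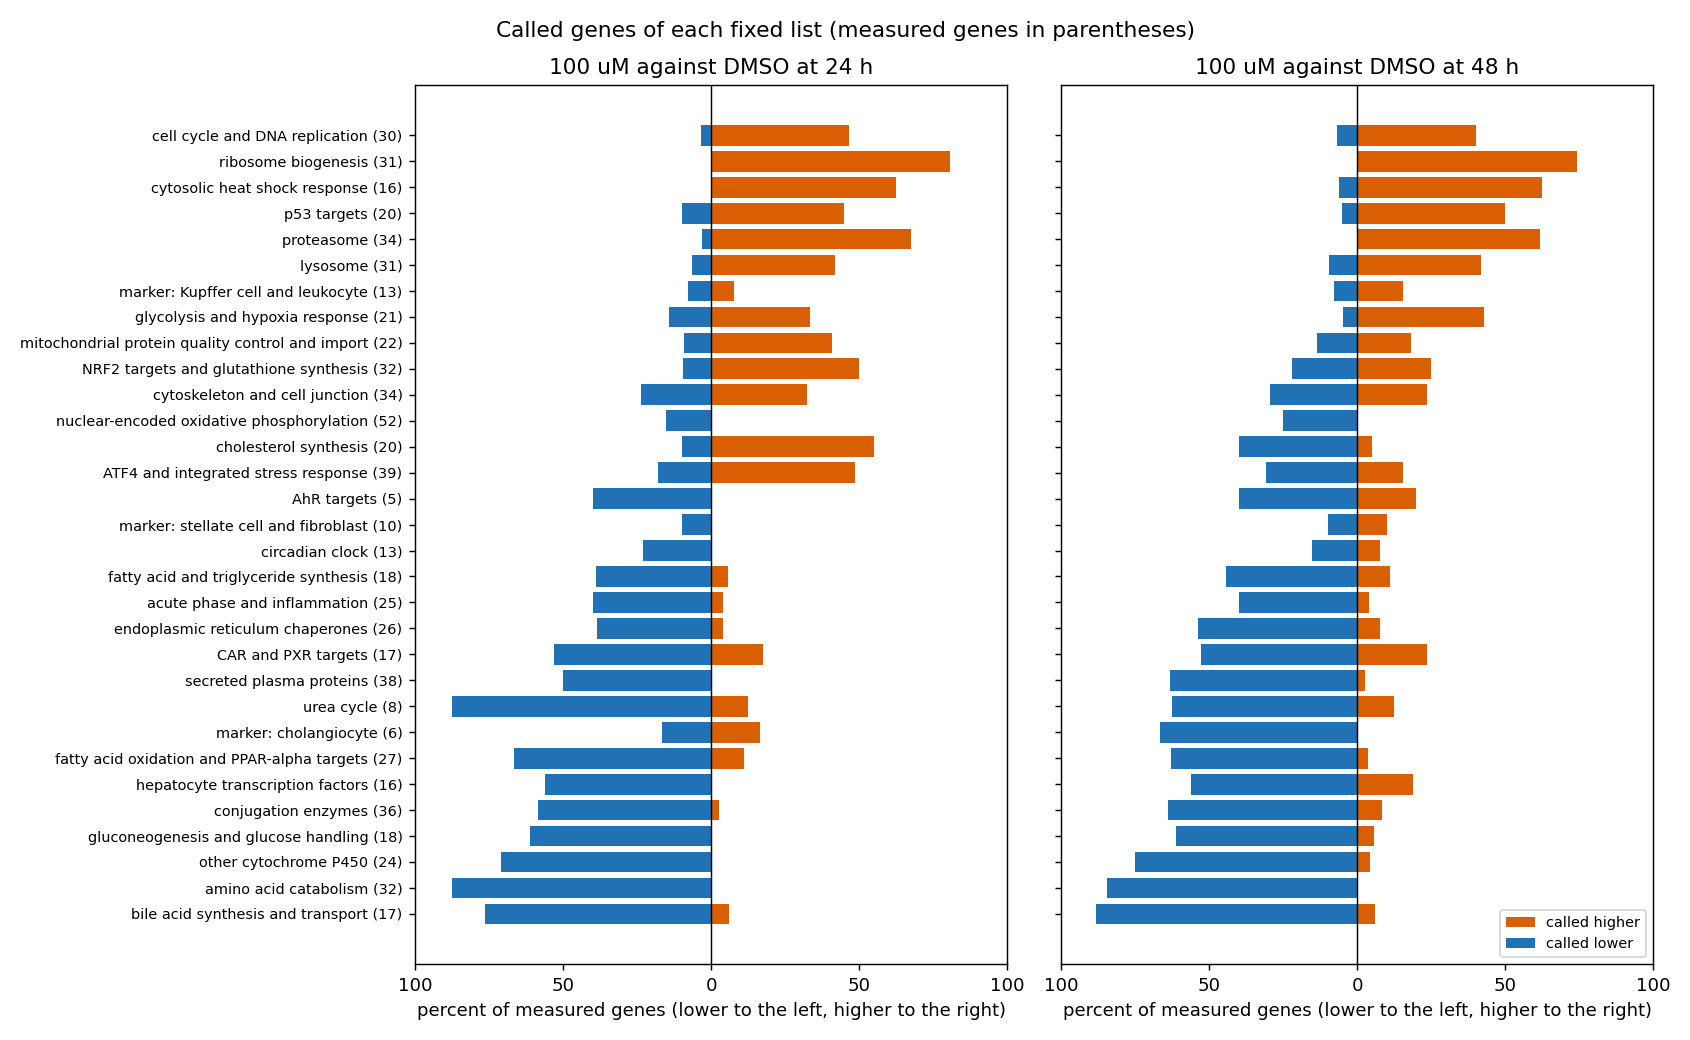
Bars show the percent of each list's measured genes called higher (to the right) or lower (to the left) at 100 uM against DMSO, at 24 h and at 48 h, with the number measured in parentheses, ordered by the median change at 48 h. Amino acid catabolism has 28 of 32 genes lower at 24 h and 27 of 32 at 48 h.

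Most of the 100 uM response was shared by the 2 times. Of the genes called at both, 1353 rose and 1110 fell at both times, where independent lists would share 383 and 235, and 12 went in opposite directions. Across the 10222 genes, which are not independent replicates, the log2 fold changes at 24 and 48 h, from separate controls, correlated at r = 0.750. The simulated value for unchanged groups was -0.00230.

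**Figure D4:**
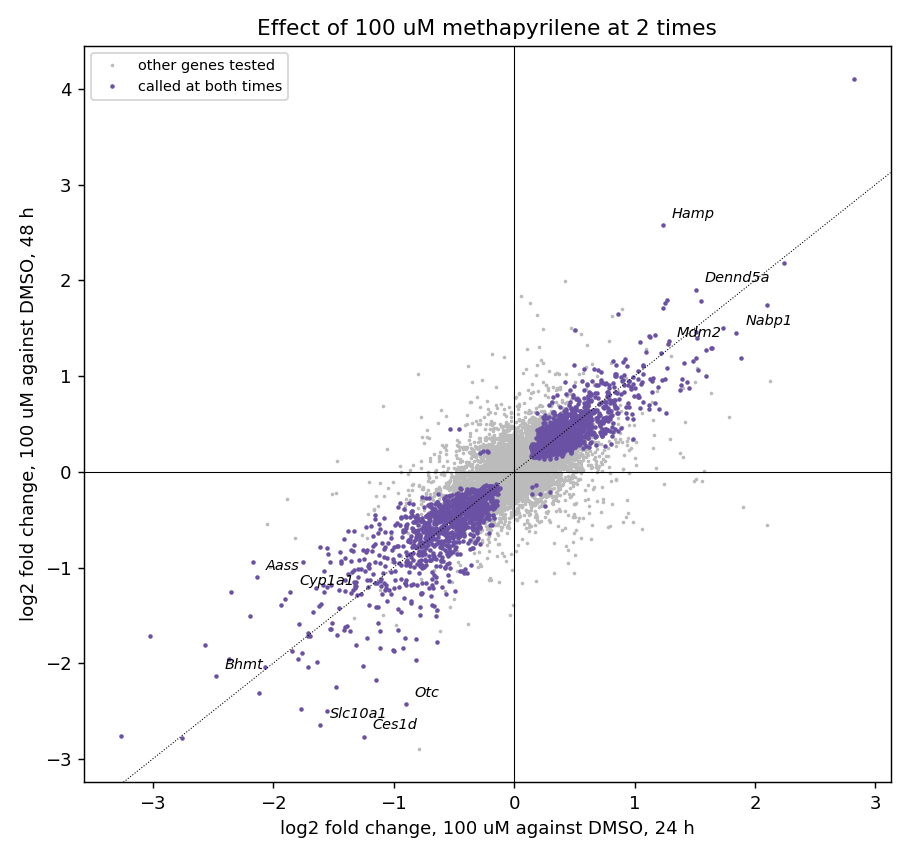
Each point is one of the 10222 genes tested, with its log2 fold change at 100 uM against DMSO at 24 h on the horizontal axis and at 48 h on the vertical axis; purple points were called at both times and the dotted line marks equal change. Otc and Ces1d lie below the line and Hamp above it.

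The size of the effect changed with time for some genes. These differences also hold the change of the DMSO wells over time. Hamp signals in DMSO lay between 2342 and 2637 at 24 h and between 1148 and 1889 at 48 h. At 100 uM they lay between 4925 and 8300, then between 6457 and 11027. List medians in DMSO changed by 0.19 (cholesterol synthesis), 0.12 (ATF4), 0.044 (NRF2), -0.11 (other P450) and -0.094 (hepatocyte transcription factors). Otc fell further at 48 h than at 24 h, by a difference of -1.53 ± 0.25 (adjusted p = 0.000491), as did Ces1d (-1.52 ± 0.19), Pemt, which makes phosphatidylcholine (-1.22 ± 0.30), Fabp1 (-1.15 ± 0.14), Dhrs7l1 (-1.14 ± 0.24) and Slc10a1 (-1.04 ± 0.18). Hamp rose further (1.34 ± 0.20, adjusted p = 0.000113), and the effect on Aass moved up by 1.04 ± 0.13, on the neuropeptide gene Npy by 1.18 ± 0.26, on Idua by 0.98 ± 0.23, on Il1r2 by 0.98 ± 0.25 and on Serpina3c by 0.92 ± 0.14. Of these genes Il1r2 kept the call under 30 of 44 alternatives (adjusted p up to 0.0828) and Pemt under 35 (up to 0.0803). The effect on cholesterol synthesis genes moved down between the times (median -0.31, adjusted p = 7.59e-14): 5 of 20 moved down and 0 up, or 13 and 0 adjusted over the list alone. The same held for the ATF4 genes (median -0.23, adjusted p = 1.41e-12), of which 9 of 39 moved down and 0 up, or 14 and 0 adjusted over the list alone, and for the other P450 genes (median -0.22, adjusted p = 4.94e-06), of which 6 of 24 moved down and 0 up, or 6 and 1 adjusted over the list alone. The effect on the hepatocyte transcription factors moved up (median 0.28, adjusted p = 0.0109), with no member past the test over all genes and 4 up and 1 down adjusted over the list alone. The NRF2 list moved down (median -0.14, adjusted p = 5.80e-07, and adjusted p = 0.0770 with an estimated correlation), of which 2 of 32 moved down and 0 up, or 2 and 0 adjusted over the list alone.

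Of the 31 lists tested, 11 were called, 1 upward and 10 downward, 4 of them with an estimated correlation. In all, the effect of 100 uM differed between the times for 169 genes in the limma interaction, 63 upward and 106 downward. The count was 58 with each array centred on its median and 266 without the 3 arrays of 3 uM at 24 h that stood apart, which enter only through the shared spread.

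At 3 uM and 24 h, Cyp1a1 and Cyp1a2, P450 enzymes controlled by the aryl hydrocarbon receptor (AhR), were lower. Cyp1a1, with the smallest adjusted p of the genes named, fell from 30122 to 19499 (-0.64 ± 0.080, adjusted p = 3.26e-05) and Cyp1a2 from 16739 to 12249 (-0.46 ± 0.096, adjusted p = 0.00832). Of the AhR targets, 3 of 5 fell and 0 rose, or 3 and 0 adjusted over the list alone (adjusted p = 0.00264), the last being Nqo1 (-0.22 ± 0.060). Genes that rose included Dennd5a (0.64 ± 0.11), Pea15 (0.63 ± 0.12), the export receptor Xpo4 (0.59 ± 0.11), the pyrimidine synthesis genes Cad (0.57 ± 0.13) and Ctps1 (0.51 ± 0.12), and the heat shock gene Hsph1 (0.57 ± 0.12). For genes as dim as Elmo2 (signal 456 ± 73.5 against 161 ± 100) and Gabrq (signal 304 ± 163 against 572 ± 55.2), also named by the rule, the size of the fold is uncertain.

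At 3 uM and 24 h, 7 of the 31 lists were called, while 4.22% of all genes were. Lists not called also held genes that passed. Of the ATF4 genes, 4 of 39 rose and 2 fell. Of the lysosome genes 4 of 31 rose, and of the cytoskeleton and cell junction genes 4 of 34, with 0 lower. The lists of p53 targets, proteasome and mitochondrial protein quality control each had 3 genes higher and 0 lower. Of the ribosome biogenesis genes, 3 of 31 rose and 1 fell, or 13 and 1 adjusted over the list alone (adjusted p = 0.00231, and adjusted p = 0.417 with an estimated correlation). Tsr1 was at 0.32 ± 0.067. Of the fatty acid and triglyceride synthesis genes, 4 of 18 rose and 0 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.0361, and adjusted p = 0.610 with an estimated correlation). Acly was at 0.27 ± 0.073 and Fads1 at 0.60 ± 0.17. Of the amino acid catabolism genes, 2 of 32 fell and 0 rose, or 5 and 1 adjusted over the list alone (adjusted p = 0.00231, and adjusted p = 0.417 with an estimated correlation). Dao was at -0.33 ± 0.092. The lists of conjugation enzymes (median -0.13, adjusted p = 5.10e-05, and adjusted p = 0.548 with an estimated correlation), oxidative phosphorylation (median -0.10, adjusted p = 5.11e-07, and adjusted p = 0.632 with an estimated correlation) and secreted plasma proteins (median -0.11, adjusted p = 0.0208, and adjusted p = 0.650 with an estimated correlation) lay lower, with 0, 1 and 1 members called lower, or 0, 0 and 1 adjusted over the list alone. In the last list 1 gene was called higher, also adjusted over the list alone. Of the 7 lists called, only the AhR targets kept the call with replicates 4 and 5 alone: 3 lost it, and the mean of the 3 lists of conjugation enzymes, oxidative phosphorylation and plasma proteins had the opposite sign, 0.0249, 0.0942 and 0.0583. With the beta-actin ratio as a covariate 3 of the 7 kept the call and 4 lost it. Replicates 1, 2 and 3 are those with the raised beta-actin ratio.

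Fitted on the groups compared only, limma called 0 genes at 3 uM and 24 h. With each array centred on its median it called 225 higher and 23 lower, and with quantile normalization 325 and 207. In the main fit over all genes, limma called 306 higher and 125 lower at 3 uM and 24 h, 19 of them by at least 1.5-fold. This count rested on replicates 1, 2 and 3: with replicates 4 and 5 alone 4 genes were called, Oprk1, Padi1, Pla2g2f and Zmpste24, none of them among the 431 (named after their values were seen), and with the beta-actin ratio as a covariate 1 was. Without replicate 1, 2 or 3 of 3 uM the count was 76, 65 and 42, without replicate 4 or 5 it was 1451 and 1650, and without replicate 1, 2 or 5 of DMSO it was 267, 126 and 244. Cyp1a1 was at -0.38 ± 0.079 (adjusted p = 0.0574) and Cyp1a2 at -0.24 ± 0.12 (adjusted p = 0.520) with replicates 4 and 5 alone, and over all 44 alternatives their adjusted p ranged from 3.04e-09 to 0.216 and from 2.25e-05 to 0.546.

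At 3 uM and 48 h, Cyp1a2 fell from 9119 to 5641 (-0.69 ± 0.096, adjusted p = 0.000360) and Cyp1a1 from 31748 to 23764 (-0.42 ± 0.080, adjusted p = 0.0308). Rrp9, a ribosomal RNA processing factor, rose (0.82 ± 0.14, adjusted p = 0.00488), as did Ift52, of the transport inside cilia (0.49 ± 0.094, adjusted p = 0.0308). These were the 4 genes that limma called. Of the AhR targets, 2 of 5 fell and 0 rose, or 2 and 0 adjusted over the list alone (adjusted p = 1.53e-05). Camera placed 8 further lists past the threshold, with 0 members called in 7 of them and 1 in ribosome biogenesis (0 or 1 adjusted over the list alone), and none kept the call with an estimated correlation. They were amino acid catabolism (median -0.061, adjusted p = 0.00513, and adjusted p = 0.299 with an estimated correlation), ribosome biogenesis (0.060, adjusted p = 0.00620, and adjusted p = 0.320 with an estimated correlation), other P450 (-0.049, adjusted p = 0.0207, and adjusted p = 0.221 with an estimated correlation), proteasome (0.048, adjusted p = 0.0346, and adjusted p = 0.660 with an estimated correlation), bile acids (-0.051, adjusted p = 0.0363, and adjusted p = 0.479 with an estimated correlation), conjugation enzymes (-0.039, adjusted p = 0.0363, and adjusted p = 0.662 with an estimated correlation), plasma proteins (-0.023, adjusted p = 0.0445, and adjusted p = 0.662 with an estimated correlation) and heat shock (0.049, adjusted p = 0.0490, and adjusted p = 0.221 with an estimated correlation). The 522 genes with an unadjusted p under 0.05 compare with 511 expected by chance. Cyp1a2 passed under all 44 alternatives, Rrp9 under 43, Cyp1a1 under 33 and Ift52 under 32, with adjusted p from 7.30e-06 to 0.00461, 0.00115 to 0.0705, 0.000384 to 0.194 and 0.00894 to 0.302. Leaving out any replicate of 3 uM, or replicate 2, 3 or 5 of DMSO, at 48 h left 2 calls.

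At 100 uM, Cyp1a1 changed by -1.86 ± 0.080 at 24 h and -1.26 ± 0.080 at 48 h, and Cyp1a2 by -0.69 ± 0.096 and -1.30 ± 0.096. Among the other AhR targets, Tiparp rose at 48 h (0.27 ± 0.082, adjusted p = 0.0114, or 0.0650 with each array centred on its median), and the list was called lower at 24 h although its median was positive (0.055, adjusted p = 0.0459, and adjusted p = 0.105 with an estimated correlation). At 48 h the list was lower as well (median -0.13, adjusted p = 0.0202, and adjusted p = 0.0401 with an estimated correlation): 2 of 5 fell and 1 rose, or 2 and 1 adjusted over the list alone. Between the doses at 24 h, Cyp1a1 differed by -1.22 ± 0.080 (adjusted p = 8.15e-14), Bhmt by -2.12 ± 0.11 and Mdm2 by 1.21 ± 0.060, while Cyp1a2 did not pass the test (-0.23 ± 0.096, adjusted p = 0.0585). At 48 h, Cyp1a1 differed by -0.84 ± 0.080, Cyp1a2 by -0.61 ± 0.096 (adjusted p = 6.65e-06) and Mdm2 by 1.22 ± 0.060. Limma called 2021 genes higher and 1949 lower at 100 uM than at 3 uM at 24 h, and 1656 and 1289 at 48 h. At 24 h the upward share was 34.5% of the calls with each array centred on its median, against 50.9%, and at 48 h 49.6% against 56.2%. The 24 h count was 2440 with the beta-actin ratio as a covariate.

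Some genes were called at both doses. At 24 h, 126 genes rose and 47 fell at both doses, where independent lists would share 60.7 and 19.8, and 39 went in opposite directions. Both doses were compared with the same DMSO arrays, which alone gave a simulated correlation of 0.501 and a covariance of 0.0160, against 0.269 and 0.0234 observed across genes. With the DMSO arrays split between the doses the correlation was 0.0700 on average over 20 splits. At 48 h the observed correlation was 0.391 (0.512 simulated, 0.147 with split controls) and the covariance 0.0257 (0.0164 simulated). Between 24 and 48 h at 3 uM, Cyp1a1 and Cyp1a2 were the 2 genes called at both times, and the correlation across genes was 0.0470. No difference of the 3 uM effect between the times was called (limma interaction, 0 genes, 1256 with an unadjusted p under 0.05 against 511 expected), though 1616 were called with array weights, which give less weight to arrays that fit poorly. Without replicate 4 or 5 of 3 uM at 24 h, 44 and 153 were called. The lists of cholesterol synthesis (median -0.12, adjusted p = 0.00987, and adjusted p = 0.857 with an estimated correlation), fatty acid and triglyceride synthesis (-0.19, adjusted p = 0.00987, and adjusted p = 0.857 with an estimated correlation) and oxidative phosphorylation (0.13, adjusted p = 5.48e-08, and adjusted p = 0.857 with an estimated correlation) differed between the times, with 0 members called, or 1, 1 and 0 adjusted over the list alone. None of the 3 kept the call with replicates 4 and 5 of 3 uM at 24 h alone, where 2 lost it and oxidative phosphorylation reversed, or with the beta-actin ratio as a covariate.

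In the DMSO wells, culture from 24 to 48 h changed hepatocyte genes too. Cyp3a2 fell from 6203 to 1615 (-1.96 ± 0.11, adjusted p = 2.75e-15), the male-specific Cyp2c13 from 6237 to 1729 (-1.85 ± 0.090), Serpina3c from 19394 to 4919 (-1.99 ± 0.10) and Serpina6, the corticosteroid binding globulin, from 2417 to 547 (-2.15 ± 0.14). The desaturase Scd2 rose from 640 to 2651 (2.06 ± 0.12, adjusted p = 1.51e-14) and Acta1, a muscle actin, from 2893 to 9229 (1.66 ± 0.15). Of the other P450 genes, 6 of 24 fell and 0 rose, or 6 and 0 adjusted over the list alone (adjusted p = 3.92e-06), and of the cholangiocyte markers 3 of 6 rose and 0 fell, or 4 and 0 adjusted over the list alone (adjusted p = 1.68e-05). Of the genes of fatty acid oxidation, 7 of 27 rose and 1 fell, or 13 and 1 adjusted over the list alone (adjusted p = 1.61e-06, and adjusted p = 0.0703 with an estimated correlation), and of cholesterol synthesis 8 of 20 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 1.68e-05, and adjusted p = 0.0703 with an estimated correlation). Lower too were the Kupffer cell and leukocyte markers (1 of 13 fell and 0 rose, or 1 and 0 adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.106 with an estimated correlation), the AhR targets (2 of 5 fell and 0 rose, or 2 and 0 adjusted over the list alone; adjusted p = 0.00594) and the hepatocyte transcription factors (2 of 16 fell and 0 rose, or 2 and 0 adjusted over the list alone; adjusted p = 0.00594). The ATF4 list was higher, with 7 of 39 genes up and 2 down, or 9 and 2 adjusted over the list alone (adjusted p = 0.000321, and adjusted p = 0.0703 with an estimated correlation). The 15 lists called were 7 upward and 8 downward, and 4 were called with an estimated correlation. In all, limma called 263 genes higher and 195 lower at 48 h, and 243 in total with each array centred on its median.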

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

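Chosen only after the result was seen were the tests on hepatocyte metabolic genes at 100 uM, the tests for a wrong label, and the count with replicates 4 and 5 of 3 uM at 24 h alone. The tests of RNA quality and of the sign at 48 h were chosen after the arrays of 3 uM at 24 h stood apart, before their own values were seen. The splits were planned.

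The 431 genes called at 3 uM and 24 h rested on replicates 1, 2 and 3, since replicates 4 and 5 alone gave 4. A wrong label within the series as the whole cause was argued against. The median number of called genes between the 3 arrays and pairs of arrays of each other group was 2209 or more. It was lowest for DMSO at 24 h. Splits of 3 and 2 arrays inside the other groups gave 33 at most. The 3 arrays were picked because they stood apart, so a high count was likely in advance. It cannot exclude a wrong label together with another fault, such as low RNA quality. By distance 0 of the 3 lay nearest to a group other than DMSO at 24 h. Their distances to its pairs (0.383, 0.382 and 0.414) were below those to replicates 4 and 5 (0.407, 0.411 and 0.443). For 2 of the 3 this was as near as the farthest of the other arrays to pairs of its own group (0.412). DMSO arrays under a wrong label cannot by themselves account for differences from DMSO. Samples from outside the series were not tested and stay open. A response that was also there at 48 h may account for part of it, since 68.0% of the called genes had the same sign at 3 uM and 48 h, where unchanged groups gave a median of 49.4% and 0 of 100 draws as many. RNA quality cannot be told apart from it. The fold changes correlated at 0.136 across genes with slopes on the beta-actin ratio in 20 other arrays, and 25 of 100 shuffles gave as much. No other array had a beta-actin ratio above 3.43, against 3.93 to 5.30 in the 3 arrays, which keeps this open. The GAPDH ratio was the highest of all arrays in replicates 2 and 3 (1.21 and 1.24).

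At 100 uM the genes of amino acid catabolism fell together, 27 of 32 at 48 h. Scaling was argued against, with a median no higher than -0.87 (SE 0.16) over 3 scalings. RNA quality, as far as the beta-actin ratio measures it, was argued against too, since the ratio was much alike in the groups. It was 2.84 ± 0.38 at 100 uM and 2.63 ± 0.15 in DMSO. The same 27 were called lower with this ratio as a covariate, at a median of -0.88 (SE 0.17). A covariate so alike in the groups could move this comparison little. The 3' to 5' ratio of the GAPDH control did differ at 48 h. It was 1.058 ± 0.019 at 100 uM (1.0241 to 1.0704) and 1.105 ± 0.017 in DMSO (1.084 to 1.129). It was lower at 100 uM and was not tried as a covariate, so RNA quality by this control was not tested. A loss of hepatocyte RNA that strikes every gene alike was argued against, and with it a lower share of hepatocytes as the whole cause. Under a signal of 20000 the median of 12 secreted plasma protein genes lay 0.57 (SE 0.19) above that of 27 amino acid catabolism genes. Without a limit the difference was 0.59 (SE 0.17). These errors take the genes of a list as independent. The amino acid list was chosen after its fall was seen and had the smallest camera adjusted p at 48 h (2.12e-25). Some gap to another list was thus likely in advance, which makes this weak evidence. A lower share as part of the cause cannot be told apart, since the marker lists of other cells moved apart by less than 2 standard errors of their difference (0.29 for the widest gap), with medians of -0.30 (SE 0.26) for cholangiocytes, -0.15 (SE 0.13) for stellate cells and 0.17 (SE 0.11) for Kupffer cells. The fall went with the 100 uM dose in separate wells at both times. Whether it was a regulated response of the cells, or in part a lower share of hepatocytes, stays open.

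Chance was tested with 100 splits of the arrays for each comparison, the real one included. For 3 uM at 24 h chance could not be excluded: 16 splits called as many genes as the 431, up to 1699, which points to a structure of the samples. At 3 uM and 48 h only the real split called as many genes (1 split, 4 genes, highest other 2). By the planned rule this argued against chance for the count of 4 genes, though by a narrow margin. Beyond these genes, 522 at an unadjusted p under 0.05 in limma against 511 expected gave no sign of a wider change. Chance could be excluded for 100 uM at 24 h (1 split, 3647 genes, highest other 1338) and at 48 h (1 split, 3415 genes, highest other 929). The same held between the doses at 24 h (1 split; 3970, highest other 2635) and at 48 h (1 split; 2945, highest other 920), and for DMSO over time (1 split; 458, highest other 12). For the change of the 100 uM effect between times these splits cannot decide on chance, which stays open. There 6 splits were as large as 169, with a highest other of 1988. Labels were shuffled within each time, so the effect of the dose itself enters the shuffled difference. For the change of the 3 uM effect the real count in limma was 0, with 1256 genes at an unadjusted p under 0.05. All 100 splits were thus as large, the highest at 236. High counts in other splits of 100 uM and of its interaction mix treated with control arrays, so they hold the dose effect.

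Single arrays stood far from the other 4 of their group in 10 of 72 tests, where chance gives about 1 in 20, or 3.6. The median signal was lowest in replicate 3 of DMSO at 24 h (361.677) and in replicate 1 of DMSO at 48 h (381.492). The 3' to 5' ratio of GAPDH was lowest in replicate 2 of 100 uM at 48 h (1.0241). The mean correlation with the own group was lowest in replicate 5 of 3 uM at 48 h (0.976039) and in replicate 3 of 100 uM at 48 h (0.970695). In replicate 5 of DMSO at 48 h the signals of Cyp1a1 (35271.5) and Cyp1a2 (10527.2) were the highest of the group and that of Mdm2 (2998.21) the lowest. Mdm2 was also lowest in replicate 5 of 3 uM at 24 h (3429.21), and Slc10a1 highest in replicate 2 of 100 uM at 24 h (2338.42).

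The effect of 100 uM differed between 24 and 48 h by a limma interaction for 169 genes. The log2 difference was 1.34 for Hamp, 1.18 for Npy, 1.04 for Aass, 0.98 for Idua, 0.98 for Il1r2 and 0.92 for Serpina3c. It was -1.53 for Otc, -1.52 for Ces1d, -1.22 for Pemt, -1.15 for Fabp1, -1.14 for Dhrs7l1 and -1.04 for Slc10a1. Among the 4025 probe sets that are not assigned to exactly 1 gene, 908 were called at 100 uM and 24 h and 860 at 48 h.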

How the results depend on the processing

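The replicates 4 and 5 alone setting and the beta-actin covariate were chosen after seeing the data. Of the gene counts under alternatives other than a left-out array, 127 stayed within 1.5 times the main count and 26 did not, and named genes kept direction and side of the threshold in 5858 comparisons, lost the call in 344, gained one in 12 and reversed in 6. With each array centred on its median the counts were 248 (3 uM, 24 h), 2 (3 uM, 48 h), 58 (change of the 100 uM effect) and 243 (DMSO time), and with all probe sets 6060 between the doses at 24 h. Array weights gave 2889 at 3 uM and 24 h, 261 and 1616 for the changes of the 100 and 3 uM effects and 692 for DMSO time. Fitted on the groups compared only, limma called 0 at 3 uM and 24 h, with 1473 at an unadjusted p under 0.05. Replicates 4 and 5 alone gave 4, and 266 for the change of the 100 uM effect; 1 gene was then shared with 100 uM at 24 h (173 before) and 0 with 3 uM at 48 h (2 before). The covariate gave 1 at 3 uM and 24 h and 2440 between the doses. Requiring 1.5-fold left 19, 969, 2 and 857 in the dose comparisons, 1001 and 662 between the doses, 67 and 104, and an adjusted p under 0.01 left 54 and 2 at 3 uM, 63 for the change of the 100 uM effect and 241 for DMSO time; fewer genes pass stricter limits by construction. Lists called with an estimated correlation were 1, 11, 1, 15, 4, 0 and 4, with fry 1 (3 uM, 48 h), 6 and 0 (the changes), and with the covariate 4 (3 uM, 24 h) and 0 (its change). Upward shares under median centring were 90.7% of the calls at 3 uM and 24 h against 71.0%. With replicates 4 and 5 alone, list means at 3 uM and 24 h reversed for conjugation enzymes (0.0249), oxidative phosphorylation (0.0942, and -0.0659 for its change) and plasma proteins (0.0583, or 0.0245 with quantile normalization), as did Gsr (0.082) and Lipa (-0.00307). With the mean of a gene's probe sets Hspa9 (-0.16), Lamp1 (-0.050), Yme1l1 (-0.00796) and Psmd9 (-0.049) reversed. Leaving out 1 array gave 42 to 1650 at 3 uM and 24 h, 3260 to 3771 at 100 uM and 24 h, 2 to 4 and 3110 to 3553 at 48 h, 3538 to 4198 and 2579 to 3084 between the doses, 118 to 199 and 0 to 153 for the changes and 329 to 516 for DMSO time. Beyond what an alternative's construction shows, the cause was not tested. Signal over background was not measured, and dim genes had the widest errors.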

Other observations

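The tests on Cyp1a1 and Cyp1a2, and the fit with replicates 4 and 5 of 3 uM at 24 h alone, were chosen only after the result was seen.

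Some lists that were not called at 100 uM still held genes that passed. Over all genes 35.7% were called at 24 h and 33.4% at 48 h, so such genes would be found in most lists. Of the cytoskeleton and cell junction genes, 11 of 34 rose and 8 fell, or 13 and 8 adjusted over the list alone at 24 h (adjusted p = 0.458, and adjusted p = 0.685 with an estimated correlation), with the tubulin Tubb6 higher (0.82 ± 0.066) and the connexin Gjb1 lower (-0.80 ± 0.079). Of the glycolysis and hypoxia genes, 9 of 21 rose and 1 fell, or 10 and 1 adjusted over the list alone at 48 h (adjusted p = 0.0589, and adjusted p = 0.524 with an estimated correlation). Pfkfb3 was at 0.94 ± 0.17 and the glucose transporter Slc2a1 at 0.63 ± 0.11. Of the genes of mitochondrial protein quality control and import, 9 of 22 rose and 2 fell, or 11 and 2 adjusted over the list alone at 24 h (adjusted p = 0.143, and adjusted p = 0.373 with an estimated correlation). The import receptor Tomm70 was at 0.44 ± 0.069 and the protease subunit Clpx at -0.58 ± 0.060. Of the circadian clock genes, 3 of 13 fell and 0 rose, or 3 and 0 adjusted over the list alone at 24 h (adjusted p = 0.106, and adjusted p = 0.278 with an estimated correlation). Npas2 was at -0.90 ± 0.13.

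Methapyrilene blocks a histamine receptor, and the list of histamine genes had too few measured members for a test. Maob, a monoamine oxidase, fell at 100 uM by -0.54 ± 0.071 at 24 h and -0.70 ± 0.071 at 48 h, and Maoa by -0.18 ± 0.068 and -0.37 ± 0.068. The Maoa call at 24 h was kept under 36 of 44 alternatives (adjusted p up to 0.114). Among the markers of sinusoidal endothelial cells, Esam rose at 24 h (1.89 ± 0.40, signal 652 ± 155 against 196 ± 111). Its DMSO signal lay below the array medians, so the size of the fold is uncertain. Of the stellate cell and fibroblast markers, 1 of 10 rose and 1 fell, or 1 and 1 adjusted over the list alone at 48 h (adjusted p = 0.346, and adjusted p = 0.519 with an estimated correlation). Lox, which crosslinks collagen, was at -1.18 ± 0.13.

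Cyp1a1 and Cyp1a2 were lower at both doses and both times. At 3 uM and 24 h the Cyp1a2 call rested on the 3 arrays that stood apart. With replicates 4 and 5 alone it was at -0.24 ± 0.12 (limma adjusted p = 0.520). Cyp1a1 was then at -0.38 ± 0.079 and also lost its call (limma adjusted p = 0.0574). Its signals in replicates 4 and 5 (21176 and 25200) still lay below all 5 DMSO arrays (27579 to 32243). Over the 44 alternatives the Cyp1a1 call was kept under 42 and the Cyp1a2 call under 40. Most of these leave out 1 array, often of a group outside the comparison, and so change little. Fitted on the groups compared only, both calls were lost. At 3 uM and 48 h a general loss of P450 transcripts was argued against, since the other 34 P450 genes had a median of -0.060. Scaling was argued against there as the source of the sign, since the least negative change over 3 scalings was -0.42 (SE 0.080, Cyp1a1 as deposited); centred on array medians Cyp1a1 was at -0.45 (SE 0.090) and lost its call (adjusted p = 0.0624) as its spread widened. At 100 uM Cyp1a1 lay 1.30 (SE 0.15) below the median of the other P450 genes at 24 h and 0.52 (SE 0.16) at 48 h. Cyp1a2 lay 0.12 (SE 0.16) below it at 24 h and 0.56 (SE 0.17) at 48 h. These errors do not cover the spread between single P450 genes. At 48 h Cyp2a1 and Cyp3a18 fell further than both, so a general loss stays open there, and for Cyp1a2 at 24 h. The gap was widest for Cyp1a1 at 24 h, but its place in that spread was not tested. Lower activity of AhR may lie behind the change, but its other targets leave this open, with a median of 0.19 at 100 uM and 48 h over 3 genes, of which Tiparp rose.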
